A study of Mus musculus with 9 samples.

How the data were processed

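What was measured is gene expression in single cells of hindpaw-engrafted B16F10 melanomas from mice on a mattress (4 libraries) or after forced wheel running (5 libraries). Per the labels' protocols, tumours were chopped, dissociated with an enzyme kit and freed of red cells by lysis, and libraries were made with the 10x 3' v3 kit. The values the authors deposited are UMI counts per gene and barcode, made with Cell Ranger 6.0.2 on the mm10 build, per the submitters' processing notes. The annotation release and whether barcodes had been called as cells are not given in the sources used here. The lowest barcode of a library held between 500 and 1195 UMIs, so low barcodes had been removed before. The features numbered 32285 in the B16F10 libraries and 32286, with mCherry, in the others. Gene coordinates were taken from GENCODE vM21 on GRCm38, the assembly that mm10 names, by matching gene identifiers.

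Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which left 134556. Doublets were scored with scrublet as run in scanpy 1.11.5. Its automatic threshold failed in both B16F10 libraries, where it called 0.0106% and 0.0172% of cells, so in every library the highest scores were removed up to 0.8% per 1000 barcodes. That rule was chosen after the scores were seen. It removed 23109 cells, between 5.46% and 24.6% per library, and left 111447. Depth per library lay between 105234259 and 381543748 UMIs, and the median kept cell held between 3421 and 14194 UMIs.

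Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes, 30 principal components and 15 neighbours, Leiden clustering at resolution 1 gave 20 clusters, with no integration of libraries. Clusters were named with 22 fixed marker lists: a host cluster needed a mean log2 fold of at least 1.5 over the markers, at least 3 markers raised 2-fold and 1 among its top 10 genes. A melanoma cluster needed at least 3 melanoma markers raised over host cells, a median depth of at least 1/3 relative to its libraries and fewer than 3 markers of another class on top. One melanoma cluster, of 8905 cells, had a median of 3011 UMIs, 0.363 relative to its libraries, and 10.9% mitochondrial UMIs. Host cells were clustered again into 20 groups and lymphoid cells into 12. Clusters that met neither rule stayed unnamed. Because unnamed clusters carried mCherry and Pmel, they were left out of the share among cells other than melanoma cells, which was decided after the data were examined.

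Counts were summed per library and class, for libraries with at least 20 cells of the class and classes with at least 3 such libraries per group. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) under R 4.3.3, with cell line and treatment as terms and Benjamini-Hochberg adjustment, at a threshold of 0.05. A set of 35 lists was tested in 5 classes and in whole libraries with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a class. List members counted "adjusted over the list alone" come from edgeR's p-values. Shares of cells, and differences of list means between classes, were tested with two-sided exact permutation tests over all relabellings of the libraries. mCherry was described after thinning each cell to 1000 UMIs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.

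The tests, their covariates, the lists, the markers and the rule for named genes were chosen before the data were examined. The rule names, per class, up to 10 genes per direction that pass with a mean of at least 10 CPM, or, where fewer than 5 pass, the 5 of that direction with the smallest p. It leaves out mitochondrial and ribosomal protein genes and unnamed gene models. It adds the 4 members with the smallest p of each list described, and Lmna, Lmnb1, Cgas, Sting1 (Tmem173 in these files) and mCherry whatever their value. Genes named outside the rule are marked as chosen after their values were seen. Some genes that these rules would name are not reported here.

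The tests were checked on simulated counts with 200 changed genes, drawn from the real means, dispersions and library sizes. Each gene was drawn on its own, so members of a list did not vary together as they can in the data. At a 2-fold change edgeR recovered 64 of 97 genes in melanoma cells, 50 of 98 in whole libraries, 60 of 99 in macrophages and monocytes, 55 of 96 in fibroblasts and 52 of 92 in endothelial cells. In T cells it recovered 25 of 78, in neutrophils 11 of 88, in dendritic cells 34 of 88 and in NK cells 27 of 88. At a 4-fold change it recovered 95 of 98, 84 of 93, 95 of 99, 97 of 97, 91 of 91, 83 of 85, 67 of 76, 81 of 83 and 74 of 80 in the same order. Between 3 and 12 unchanged genes were called, among 1803 to 16504 genes per class. Camera called 2 of 2 lists of 25 genes shifted by 0.5 on the log2 scale in every class, and 0 others. With an estimated correlation it called both except in T cells (1) and in neutrophils and NK cells (0).

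Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low count filter, no covariate, a replicate block, B16F10-mCherry libraries alone, each library left out in turn, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), resolution 0.5, at most 300 cells per library, camera with an estimated correlation, fry, shares on the logit scale or by edgeR on cell counts, list differences as mean z-scores, and thinning to 2000 UMIs. Batch as a covariate, batches B and C alone, relabelling within batches, leaving out genes at least as high in melanoma cells, and unnamed cells in the denominator were added after the data were examined. A fit in batch B alone has 1 mattress library, which is assumed to vary like the running libraries. In gene and list tests with cell line as a term, leaving out Mattress 1 or Running 1 takes both out of the comparison of treatments. Those omissions are thus close to the same check. Mast cells, B cells, mural and erythroid cells were compared only as shares, and lists were not tested in neutrophils, dendritic cells or NK cells. Raw reads were not used here.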

Results

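Single-cell RNA libraries were made from B16F10 mouse melanomas, a pigmented tumour line, growing in the hindpaw of mice that either rested on a mattress or were made to run in a wheel. The series asks what mechanical load on a tumour does to the nuclear envelope of its cells and to the exchange between tumour and stroma. Mattress was measured in 4 libraries and running in 5. Replicate 1 of each group carried plain B16F10 cells and the other 7 libraries carried B16F10-mCherry cells, which express a red fluorescent protein. The mattress libraries 1 to 4 held 10419, 28029, 11706 and 12111 barcodes with 147, 337, 154 and 139.5 M (mega) UMIs. The running libraries 1 to 5 held 6825, 30748, 26815, 10322 and 9606 barcodes with 105, 353, 382, 162 and 152 M UMIs. The median barcode held between 3378 UMIs (Running 1) and 12989 UMIs (Mattress 1), and its median mitochondrial share lay between 2.49% (Running 2) and 7.41% (Running 1). The labels do not say whether each library came from a separate animal, so p-values here measure only the spread between libraries. Summed counts of replicates of a group differed beyond counting noise, with a chi-square per degree of freedom between 47.0 (Mattress 3 and 4) and 722 (Mattress 1 and 2).

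The libraries fell into 3 batches that the labels do not name and that were read from the data after they were examined. Batch A is replicate 1 of both groups, the plain B16F10 pair. Batch B is Mattress 2 with Running 2 and 3, each with over 20000 barcodes. Batch C is Mattress 3 and 4 with Running 4 and 5. Across melanoma cells, the leading principal component took 45.9% of the variance and set batch A apart, and the next took 21.4% and parted batches B and C. Every batch holds both treatments, so differences are also given within batches in the order A, B and C. Batch A has 1 library per group and batch B has 1 mattress library, so a difference within either has no spread of its own.

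Which cells the tumours held was asked of 111447 cells kept after filtering. They comprised 60388 melanoma-like cells, 15886 macrophages and monocytes, 7921 fibroblasts, 3198 neutrophils, 2459 endothelial cells, 1629 B cells, 1404 dendritic cells, 1235 T cells, 1223 erythroid cells, 962 mural cells, 504 NK and innate lymphoid cells, 28 mast cells and 14610 cells left unnamed. Classes are named for their resemblance to fixed marker genes, so each name stands for cells like that type. Melanoma cells were 59.2% ± 14.2 (SD, n = 4) on the mattress and 42.9% ± 10.7 (SD, n = 5) with running (exact permutation p = 0.135, adjusted p = 0.585), with within-batch differences of -33.3, -25.5 and -7.81 percentage points. Macrophages and monocytes were 10.4% ± 2.998 (SD, n = 4) on the mattress and 16.1% ± 4.96 (SD, n = 5) with running (exact p = 0.0952), with within-batch differences of 2.10, 11.2 and 3.39. Among named cells other than melanoma cells they were 43.9% ± 11.1 (SD, n = 4) and 42.0% ± 6.23 (SD, n = 5) (exact p = 0.778), with within-batch differences of -25.6, 7.60 and 2.39. That direction depends on Mattress 1, at 60.3% against 35.9% to 40.1% in the other mattress libraries, and without it the difference was 3.58 percentage points. Neutrophils were 1.70% ± 1.37 (SD, n = 4) on the mattress and 4.21% ± 2.18 (SD, n = 5) with running (exact p = 0.0714), with within-batch differences of 3.42, 1.07 and 3.48. Fibroblasts were 4.68% ± 3.10 (SD, n = 4) on the mattress and 7.67% ± 3.33 (SD, n = 5) with running (exact p = 0.183), with within-batch differences of 4.22, 8.14 and -1.94. No class passed the test after adjustment over the classes. The smallest exact p that relabelling the libraries can give is 0.00794. Adjusted over the classes, a single class at that p cannot pass, so the lack of calls by this test says little. Endothelial cells were 2.10% ± 1.24 (SD, n = 4) on the mattress and 2.42% ± 0.336 (SD, n = 5) with running while T cells were 1.37% ± 0.389 (SD, n = 4) on the mattress and 1.45% ± 1.16 (SD, n = 5) with running, differences smaller than the spread between libraries. Shares are of captured cells, which the enzymatic dissociation and the red cell lysis can set.

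Among named cells other than melanoma cells, dendritic cells were 4.66% ± 0.521 (SD, n = 4) on the mattress and 3.61% ± 0.617 (SD, n = 5) with running (exact p = 0.0317, adjusted p = 0.349), lower within each batch by the signed differences -0.583, -1.08 and -1.11 percentage points. Among all cells they were 1.21% ± 0.617 (SD, n = 4) and 1.39% ± 0.516 (SD, n = 5) (exact p = 0.667), so the direction depends on the denominator. The direction among all cells also rests on Running 4, at 2.29%. Without that library the difference was -0.0517 percentage points. Unnamed cells were 15.6% ± 8.51 (SD, n = 4) on the mattress and 18.8% ± 13.7 (SD, n = 5) with running among all cells. They were left out of the denominator of named cells.

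**Figure D1:**
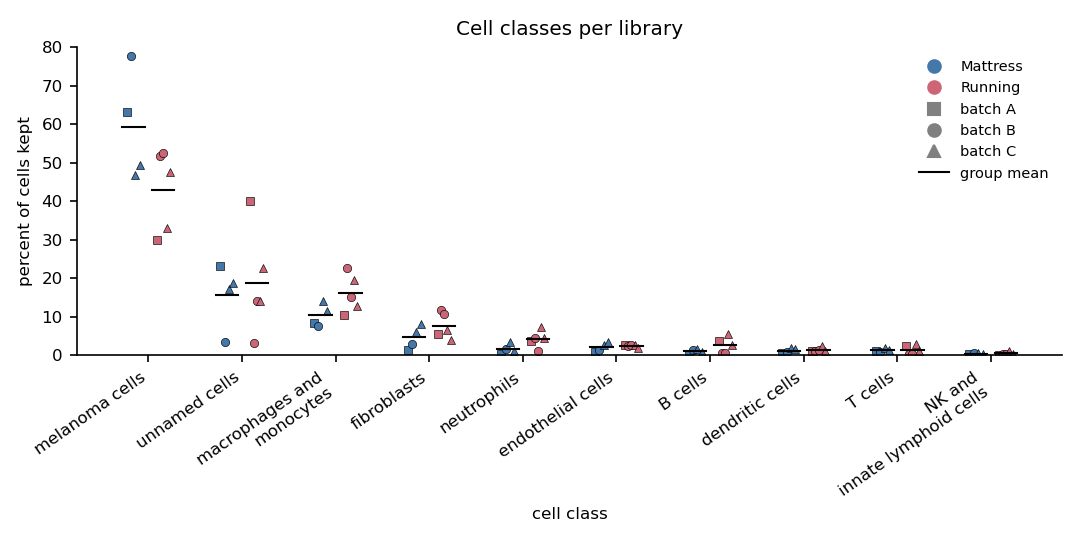
Percent of kept cells in each class (vertical axis) per library, coloured by treatment and with a marker per batch, with group means as lines. Melanoma cells averaged 59.2% on the mattress and 42.9% with running, and no class passed the exact test after adjustment. A single class could not pass that test after adjustment.

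Whether running changed the tumour cells themselves was asked in melanoma cells. Atf3, a stress-induced transcription factor, was 82.7 ± 17.8 CPM on the mattress (SD, n = 4) and 40.8 ± 7.53 CPM with running (SD, n = 5), a log2 fold change of -1.02 ± 0.18 (SE) with within-batch values of -1.70, -0.96 and -0.79. The genes of 2 small nucleolar RNA hosts were also lower: Snhg12 was 83.0 ± 8.25 CPM on the mattress (SD, n = 4) and 53.5 ± 6.08 CPM with running (SD, n = 5), and Snhg1 had a log2 fold change of -0.84 ± 0.17. Gpc1, a glypican that binds growth factors at the cell surface, was 81.6 ± 11.97 CPM on the mattress (SD, n = 4) and 116 ± 18.9 CPM with running (SD, n = 5), a log2 fold change of 0.53 ± 0.11. Slc20a1, a phosphate carrier, had 0.55 ± 0.11. None of these passed adjustment, each with adjusted p = 0.325, and each had the same sign in all 3 batches. In this class edgeR called 0 of 15089 genes at an adjusted p below 0.05, while 810 higher and 1046 lower genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.325. DESeq2 called 39 higher and 119 lower genes, and limma-voom called 0. The remaining genes with the smallest p were Fads6, Sh3bp4 and Hhipl1, with log2 fold changes of 0.56, 0.72 and 0.70, and Zfp560 and Hmgn2, with -0.55 and -0.86. On GRCm38 (GENCODE vM21), Atf3 (ENSMUSG00000026628) lies on chromosome 1, 191170296 to 191218039, Gpc1 (ENSMUSG00000034220) on chromosome 1, 92831645 to 92860779 and Snhg12 (ENSMUSG00000086290) on chromosome 4, 132308623 to 132311024.

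The genes that the question of nuclear rupture turns on were measured in the same cells. Lmna, which encodes the A-type lamins of the nuclear lamina, was 531 ± 99.5 CPM on the mattress (SD, n = 4) and 574 ± 84.8 CPM with running (SD, n = 5), a log2 fold change of 0.11 ± 0.12. Lmnb1, a B-type lamin, had 0.11 ± 0.13, Cgas, a sensor of cytosolic DNA, had 0.13 ± 0.14, and Tmem173, which encodes the adaptor STING, had -0.004 ± 0.14. As groups, nuclear envelope and rupture repair genes had a median log2 fold change of 0.03 (camera's adjusted p = 0.423), cytosolic nucleic acid sensing genes -0.01 (adjusted p = 0.86), DNA damage response and repair genes 0.04 (adjusted p = 0.86) and p53 targets -0.08 (adjusted p = 0.246). Targets of the mechanosensitive factors YAP and TAZ had 0.11 (adjusted p = 0.167), and SRF and actin cytoskeleton genes -0.02 (adjusted p = 0.559). A change of these groups was not detected in melanoma cells, where simulated lists shifted by 0.5 on the log2 scale were called in 2 of 2 cases. Those simulated genes varied independently and all moved by the same amount, so a real shift of that size could still have been missed.

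Of the 35 lists, 7 passed in melanoma cells with camera's preset correlation and 0 with an estimated correlation. Mechanosensitive channels and receptors had 16 of 17 members higher, with a median log2 fold change of 0.20 and within-batch medians of 0.24, 0.17 and 0.19. Camera's adjusted p was 0.00128, or adjusted p = 0.185 with an estimated correlation, and 0 passed adjusted over the list alone. Piezo1, a stretch-gated ion channel, went from 45.0 to 56.7 CPM, log2 fold change 0.35 ± 0.11, Ddr1, a collagen receptor, had 0.43 ± 0.13 and Adgre5 0.30 ± 0.11. TGF-beta response genes had 15 of 21 members higher, with a median log2 fold change of 0.26 and within-batch medians of 0.40, 0.12 and 0.17. The list had a camera adjusted p of 0.00196 (adjusted p = 0.185 with an estimated correlation), and 2 passed adjusted over the list alone. Pmepa1 had a log2 fold change of 0.50 ± 0.14, Skil 0.41 ± 0.16 and Smad6 0.45 ± 0.19. Limma's fry test gave both groups an adjusted p of 0.0374. The TGF-beta median was 0.17 without Mattress 3 (adjusted p = 0.0042). Immediate early genes had 18 of 23 members lower, with a median log2 fold change of -0.14 and within-batch medians of -0.18, -0.20 and -0.21. By camera this gave an adjusted p of 0.0215, with adjusted p = 0.735 with an estimated correlation, and 2 passed adjusted over the list alone. Beside Atf3, Klf2 had -0.45 ± 0.12, Jun -0.37 ± 0.15 and Jund -0.30 ± 0.12. The median of immediate early genes was -0.14 without Mattress 1 (adjusted p = 0.0653), -0.02 without Mattress 2 (adjusted p = 0.237), -0.09 without Mattress 3 (adjusted p = 0.0517), -0.24 without Mattress 4 (adjusted p = 3.79e-05), -0.15 without Running 1 (adjusted p = 0.0647) and -0.07 without Running 5 (adjusted p = 0.163). Those genes also respond to dissociation of the tissue.

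Type I interferon response genes in melanoma cells had 31 of 32 members lower, with a median log2 fold change of -0.59 and within-batch medians of 0.27, -2.11 and -0.14. By camera, the adjusted p was 1e-06, or adjusted p = 0.735 with an estimated correlation, and 0 passed adjusted over the list alone. Bst2, which tethers budding viruses, went from 377 to 255 CPM, log2 fold change -0.57 ± 0.17, Ifi44 had -2.54 ± 0.76, Ifi27 -0.39 ± 0.12 and Trim30a -1.38 ± 0.52. Melanoma cells of Mattress 2 had the highest list mean, 4.24 log2 CPM, and the median was -0.14 without Mattress 2 (adjusted p = 0.0823). Melanoma cells of Mattress 2 sat in a cluster of their own for 36.3% of their number, and those of Mattress 1 in another for 95.8%. Fibrillar collagen and matrix genes had 22 of 23 members higher, with a median log2 fold change of 0.50 and within-batch medians of 0.87, 2.18 and -0.73. The list had a camera adjusted p of 0.00322 (adjusted p = 0.752 with an estimated correlation), and 0 passed adjusted over the list alone. Tnc, a matrix glycoprotein, had a log2 fold change of 1.44 ± 0.53, Thbs1 0.76 ± 0.34, Col1a1 0.98 ± 0.45 and Col6a1 0.67 ± 0.40. Col1a1 reached 26.4 CPM in melanoma cells with running and 8605 CPM in fibroblasts. The collagen median was 0.41 without Mattress 1 (adjusted p = 0.0739), 0.25 without Mattress 2 (adjusted p = 0.28), 0.93 without Mattress 4 (adjusted p = 3.16e-07), 0.40 without Running 1 (adjusted p = 0.064) and 0.19 without Running 3 (adjusted p = 0.105). Neutrophil state genes had 15 of 19 members higher, with a median log2 fold change of 0.74 and within-batch medians of 2.06, 0.20 and 0.48. By camera this gave an adjusted p of 0.00196, with adjusted p = 0.528 with an estimated correlation, and 0 passed adjusted over the list alone. S100a8, a granule protein, went from 1.94 to 7.17 CPM, log2 fold change 1.96 ± 0.68, Camp had 5.29 ± 1.95, Cxcr2 0.74 ± 0.26 and Ccl4 -0.75 ± 0.26. Running 5 alone held 22.4 CPM of S100a8 and 8.96 CPM of Camp, against at most 4.15 and 0.194 CPM in the other libraries. The median of neutrophil genes was 0.49 without Running 1 (adjusted p = 0.0414). Both lists hold genes of host cells.

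**Figure D2:**
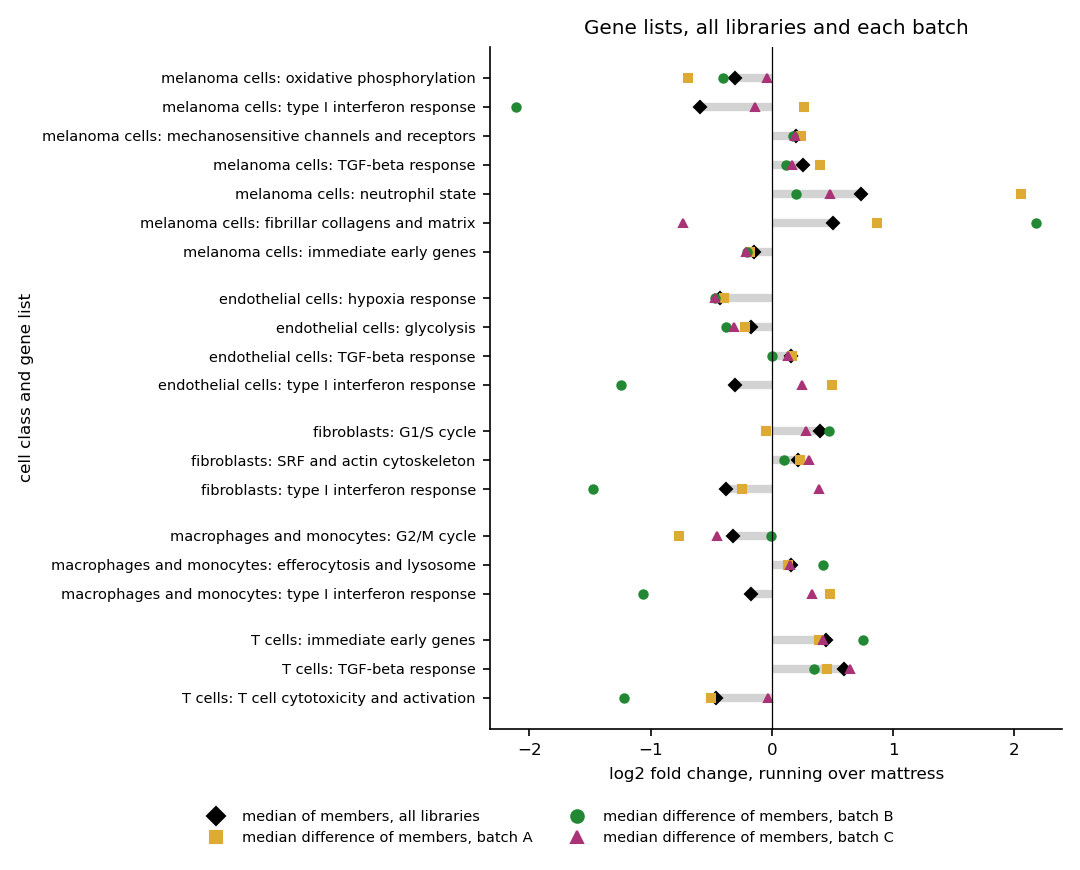
Median log2 fold change of list members over all libraries (diamonds) and median difference of members within batches A, B and C, for 20 pairs of class and list. Endothelial hypoxia response genes lay below 0 in each batch (-0.40, -0.47 and -0.46), while type I interferon response genes in melanoma cells lay at 0.27, -2.11 and -0.14.

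Nuclear-encoded subunits of the respiratory chain had lower transcript levels with running in each of 5 classes. In melanoma cells the list mean was 9.81 ± 0.15 log2 CPM on the mattress (SD, n = 4) and 9.54 ± 0.19 with running (SD, n = 5), with 27 of 28 members lower and a median log2 fold change of -0.31. The median was -0.47 in macrophages and monocytes (28 of 28 lower), -0.43 in fibroblasts (27 of 28), -0.33 in endothelial cells (28 of 28) and -0.43 in T cells (28 of 28). Camera's adjusted p was 1.11e-07, 4.67e-13, 8.08e-13, 5.38e-13 and 1.08e-10 in that order, and 0.606, 0.53, 0.557, 0.713 and 0.784 with an estimated correlation. No member passed adjusted over the list alone in these classes. Atp5o, a subunit of ATP synthase, went from 1135 to 845 CPM, log2 fold change -0.47 ± 0.13 in melanoma cells and had -0.52 ± 0.17 in macrophages and monocytes and -0.54 ± 0.16 in endothelial cells. In melanoma cells Uqcrb had -0.41 ± 0.14, Cox7b -0.61 ± 0.23 and Ndufb9 -0.36 ± 0.14.

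Within batches the respiratory chain medians were -0.69, -0.41 and -0.04 in melanoma cells, -1.08, -0.41 and -0.23 in macrophages and monocytes, -1.10, -0.37 and -0.25 in fibroblasts, -0.92, -0.32 and -0.25 in endothelial cells and -1.15, -0.28 and -0.32 in T cells, each with its largest drop in batch A. In melanoma cells the median was -0.17 without Mattress 1 (adjusted p = 6.16e-05) and -0.18 without Running 1 (adjusted p = 9.23e-05). In macrophages and monocytes it was -0.26 without Mattress 1 (adjusted p = 2.01e-09) and -0.25 without Running 1 (adjusted p = 2.14e-09), in fibroblasts -0.24 without Mattress 1 (adjusted p = 2.05e-08) and -0.24 without Running 1 (adjusted p = 2.65e-08) and in T cells -0.27 without Mattress 1 (adjusted p = 8.64e-05) and -0.23 without Running 1 (adjusted p = 0.000285). Running 1 also had the lowest median depth of kept cells, 3421 UMIs against 14194 in Mattress 1 of the same batch. Ribosomal protein genes, looked at after the data were seen, had medians of -0.38, -0.47, -0.44, -0.39 and -0.35 in the same classes, so the drop was not particular to the respiratory chain. All 28 members were at least as high in melanoma cells as in each host class.

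**Figure D3:**
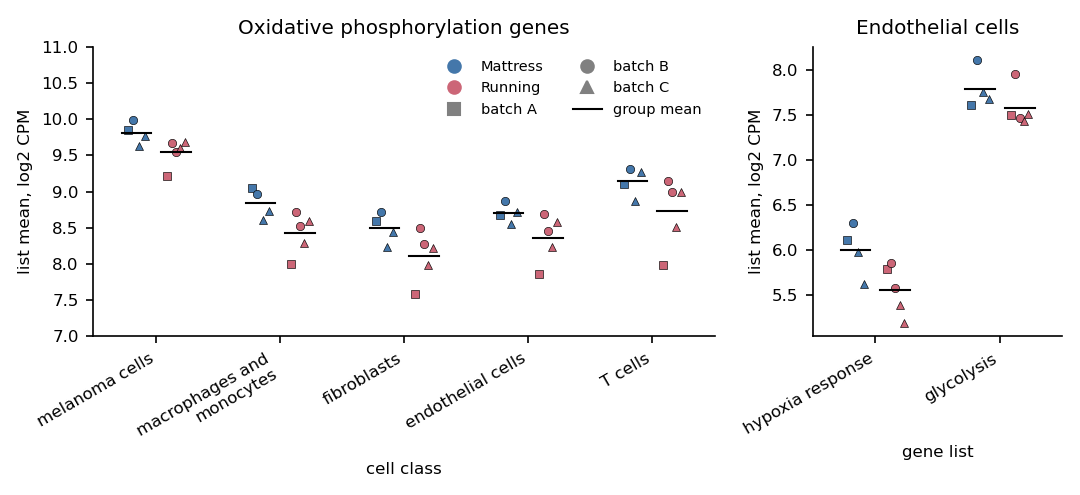
Mean log2 CPM per library of respiratory chain genes in 5 classes, and of hypoxia response and glycolysis genes in endothelial cells, by treatment and batch. The endothelial hypoxia mean was 5.9996 on the mattress and 5.56 with running.

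Endothelial cells were asked whether running changed the state of the tumour's vessels. Some HIF targets had lower values with running, though edgeR called none of them over all genes in the reported design. Ankrd37 was 149.95 ± 48.1 CPM on the mattress (SD, n = 4) and 62.1 ± 21.8 CPM with running (SD, n = 5). This gave a log2 fold change of -1.22 ± 0.25 (edgeR's adjusted p = 0.663). The lipid droplet gene Hilpda had -1.12 ± 0.27, the vasodilator gene Adm -0.95 ± 0.27 and the mitochondrial gene Higd1a -0.69 ± 0.23. The hypoxia response list was 5.9996 ± 0.29 log2 CPM on the mattress (SD, n = 4) and 5.56 ± 0.28 with running (SD, n = 5), with 18 of 21 members lower, a median of -0.42 and within-batch medians of -0.40, -0.47 and -0.46. Camera gave it an adjusted p of 1.41e-06, and adjusted p = 0.713 with an estimated correlation, and 4 members passed adjusted over the list alone. Its median was -0.16 without Mattress 2 (adjusted p = 0.0113). Glycolysis genes had 13 of 14 members lower and a median of -0.17, within batches -0.22, -0.38 and -0.31 (camera's adjusted p = 0.0039, and adjusted p = 0.713 with an estimated correlation, and 0 passed adjusted over the list alone). Their median was -0.29 without Mattress 1 (adjusted p = 5.5e-05), -0.10 without Mattress 2 (adjusted p = 0.135) and -0.29 without Running 1 (adjusted p = 6.01e-05).

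For single genes in endothelial cells, edgeR called 0 of 9892 genes at an adjusted p below 0.05, while 234 higher and 347 lower genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.163. By DESeq2, 1 higher and 3 lower genes were called, and limma-voom called 0. With batch as a covariate, edgeR called 2 genes, among them Bnip3 (log2 fold change -1.09, adjusted p = 0.0285), a HIF target named here after its value was seen. Without Mattress 4 it called Ptn, a secreted growth factor, at -2.26 (adjusted p = 0.0362) against -1.94 ± 0.38 over all libraries. Further genes with the smallest p were Cxcl12, a chemokine, at 0.99 ± 0.20, the caveolae gene Cavin1 at 0.66 ± 0.15, Ppp2r3a at 0.97 ± 0.22, Mall at 0.61 ± 0.15, Rgcc at -0.70 ± 0.15, the Notch ligand Dll1 at -0.85 ± 0.19 and Grcc10 at -0.69 ± 0.15. The enzyme genes Eno1, Ldha, Tpi1 and Pgk1 had -0.54 ± 0.22, -0.32 ± 0.14, -0.38 ± 0.17 and -0.22 ± 0.15. Lmna was 544 ± 63.3 CPM on the mattress (SD, n = 4) and 721 ± 146 CPM with running (SD, n = 5), a log2 fold change of 0.39 ± 0.18 (adjusted p = 0.818), Lmnb1 had 0.36 ± 0.26 and Cgas 0.48 ± 0.35. Ankrd37 (ENSMUSG00000050914) lies on chromosome 8, 45996902 to 46005707. Of the hypoxia list, 11 of 21 members were at least as high in melanoma cells, and without such genes its median was -0.48 (camera's adjusted p = 0.000406 with the preset correlation). With an estimated correlation the full list had an adjusted p of 0.713, so the call holds only with the preset.

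TGF-beta response genes in endothelial cells had a median of 0.16 and within-batch medians of 0.17, -0.0004 and 0.13 (camera's adjusted p = 0.0247, and adjusted p = 0.713 with an estimated correlation, and 1 passed adjusted over the list alone), which was 0.25 without Mattress 2 (adjusted p = 0.0657), 0.01 without Mattress 4 (adjusted p = 0.22) and 0.08 without Running 3 (adjusted p = 0.105). Skil had 0.44 ± 0.15, Smad3 0.44 ± 0.23 and Id1 0.39 ± 0.21. Type I interferon response genes had a median of -0.31 and within-batch medians of 0.50, -1.25 and 0.25 (camera's adjusted p = 0.0233, and adjusted p = 0.948 with an estimated correlation, and 0 passed adjusted over the list alone), which was -0.05 without Mattress 2 (adjusted p = 0.911), -0.31 without Mattress 3 (adjusted p = 0.0947), -0.18 without Running 2 (adjusted p = 0.279) and -0.16 without Running 3 (adjusted p = 0.45). Herc6 had -0.71 ± 0.27, Ifi27 -0.44 ± 0.19, Isg15 -0.65 ± 0.33 and Xaf1 -0.46 ± 0.25. A further 2 lists that passed, of MHC class I and melanocyte genes, each lost the call without at least 4 single libraries, as interferon genes did, and are not described.

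In fibroblasts the comparison asks whether load on the paw altered contractile, matrix and cycle genes of the stroma. The actin crosslinker gene Actn1 went from 199 to 267 CPM, log2 fold change 0.42 ± 0.13, non-muscle myosin Myh9 from 292 to 388 CPM, log2 fold change 0.43 ± 0.14 and the focal adhesion gene Zyx from 128 to 175 CPM, log2 fold change 0.44 ± 0.15, while Actg2 had 0.96 ± 0.40. SRF and actin cytoskeleton genes had 22 of 23 members higher, with a median of 0.22 and within-batch medians of 0.24, 0.10 and 0.30. Camera's adjusted p was 0.000176, or 0.557 with an estimated correlation, and 0 passed adjusted over the list alone. Their median was 0.39 without Mattress 2 (adjusted p = 4.24e-06). DNA replication genes of the G1/S list had 29 of 31 members higher, with a median log2 fold change of 0.39 and within-batch medians of -0.05, 0.47 and 0.28. The list's camera adjusted p was 2.31e-05, or 0.647 with an estimated correlation, and 0 passed adjusted over the list alone. Its members Cdca7, Rrm1, Mcm5 and Cdc6 had 0.89 ± 0.24, 0.41 ± 0.13, 0.62 ± 0.21 and 0.82 ± 0.31. Its median was 0.24 without Running 2 (adjusted p = 0.00809). Of the G1/S members, 30 of 31 were at least as high in melanoma cells. Mgp, an inhibitor of calcification, was the most abundant of the 5 lower genes with the smallest p that the naming rule gives, at 5755 ± 2125 CPM on the mattress (SD, n = 4) and 2360.4 ± 827 CPM with running (SD, n = 5), a log2 fold change of -1.24 ± 0.26 (edgeR's adjusted p = 0.684). Mgp (ENSMUSG00000030218) lies on chromosome 6, 136872435 to 136875823. A cluster led by Mgp held 38.9% of mattress and 26.4% of running fibroblasts (exact p = 0.294). Another with Mgp held 41.5% and 46.1%, so values mix clusters. The cycle kinase gene Cdk6 had 0.75 ± 0.15, Arl4c 0.78 ± 0.17, the actin crosslinker gene Flnc 0.63 ± 0.16, Ints2 0.63 ± 0.17 and the neutrophil gene S100a8 2.54 ± 0.59. Gngt2, Ifitm1, Smim41 and Grcc10 had -0.86 ± 0.17, -0.94 ± 0.20, -0.99 ± 0.23 and -0.76 ± 0.18.

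In fibroblasts edgeR called 0 of 11949 genes, while 369 higher and 481 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.684. DESeq2 called 4 higher and 55 lower, and limma-voom 0. Lmna was 602 ± 115 CPM on the mattress (SD, n = 4) and 747 ± 98.7 CPM with running (SD, n = 5), a log2 fold change of 0.31 ± 0.17, Lmnb1 had 0.53 ± 0.23, Cgas 0.69 ± 0.29 and Tmem173 -0.18 ± 0.23, with adjusted p between 0.69 and 0.91. DNA damage response and repair genes had 22 of 27 members higher and a median of 0.26, within batches 0.12, 0.25 and 0.19. Camera's adjusted p was 0.0451, or 0.557 with an estimated correlation, and 0 passed adjusted over the list alone. The histone gene H2afx had 0.65 ± 0.19, Rpa1 0.38 ± 0.17, Brca2 0.52 ± 0.25 and Gadd45a -0.59 ± 0.29. That median was 0.17 without Mattress 2 (adjusted p = 0.104), 0.18 without Mattress 3 (adjusted p = 0.236), 0.30 without Mattress 4 (adjusted p = 0.0922), 0.16 without Running 2 (adjusted p = 0.143), 0.25 without Running 4 (adjusted p = 0.0702) and 0.26 without Running 5 (adjusted p = 0.0543). p53 targets had 16 of 27 members lower and a median of -0.12, within batches 0.10, -0.17 and -0.20. Camera's adjusted p was 0.0451, or 0.557 with an estimated correlation, and 0 passed adjusted over the list alone. Eda2r, Fas, Cdkn1a and Gtse1 had -0.66 ± 0.28, -0.45 ± 0.20, -0.46 ± 0.22 and 0.42 ± 0.22. The p53 median was -0.15 without Mattress 2 (adjusted p = 0.221), -0.04 without Mattress 3 (adjusted p = 0.179), -0.10 without Running 2 (adjusted p = 0.0591), -0.15 without Running 4 (adjusted p = 0.0702) and -0.14 without Running 5 (adjusted p = 0.0935). Type I interferon response genes had a median of -0.38, within batches -0.25, -1.48 and 0.39 (camera's adjusted p = 2.9e-05, and adjusted p = 0.647 with an estimated correlation, and 0 passed adjusted over the list alone), which was -0.02 without Mattress 2 (adjusted p = 0.104), -0.17 without Running 2 (adjusted p = 0.0061), -0.18 without Running 3 (adjusted p = 0.0129) and -0.63 without Running 5 (adjusted p = 1.82e-11). Rsad2, Slfn5, Ifi27l2a and Ifi27 had -1.25 ± 0.41, -0.59 ± 0.20, -0.46 ± 0.17 and -0.41 ± 0.16. A further 6 lists that passed each lost the call without at least 1 library, as did DNA damage, p53 and interferon genes, and are not described. Among them were fibrillar collagens and matrix, with a median of 0.05 without Mattress 2 (camera's adjusted p = 0.321).

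For macrophages and monocytes the comparison addresses the response of the tumour's myeloid cells to load. Map4k4, a kinase of the actin cytoskeleton and of inflammation, was 102 ± 13.6 CPM on the mattress (SD, n = 4) and 166 ± 12.5 CPM with running (SD, n = 5), a log2 fold change of 0.69 ± 0.12, within batches 0.98, 0.47 and 0.73 (edgeR's adjusted p = 0.445). Ccl12, a chemokine that draws monocytes, was 1315 ± 335 CPM on the mattress (SD, n = 4) and 538 ± 228 CPM with running (SD, n = 5), a log2 fold change of -1.30 ± 0.32, within batches -2.26, -1.14 and -1.16. Map4k4 (ENSMUSG00000026074) lies on chromosome 1, 39900913 to 40026310 and Ccl12 (ENSMUSG00000035352) on chromosome 11, 82101845 to 82103400. Other genes with the smallest p were Orai2, Ptafr, Igf2r and Cdc42ep4, at 0.97 ± 0.18, 0.67 ± 0.13, 0.69 ± 0.15 and 0.73 ± 0.17, and Pkib, Ptrhd1, Zfp560 and Hmgn2, at -0.56 ± 0.12, -0.52 ± 0.12, -0.51 ± 0.12 and -0.76 ± 0.18. Over the class edgeR called 0 of 11655 genes, while 579 higher and 614 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.445. DESeq2 called 22 higher and 67 lower, and limma-voom 0. Lmna had 0.34 ± 0.17, Lmnb1 0.07 ± 0.15, Cgas 0.14 ± 0.15 and Tmem173 0.11 ± 0.20.

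Lists of the same cells gave 11 calls with camera's preset correlation, 0 with an estimated correlation and 0 by fry. Mechanosensitive channels and receptors had 11 of 13 members higher, with a median of 0.20 and within-batch medians of 0.48, 0.05 and 0.12. Camera's adjusted p was 0.0118, or 0.53 with an estimated correlation, and 2 passed adjusted over the list alone. Adgre5, an adhesion receptor, went from 58.7 to 94.8 CPM, log2 fold change 0.71 ± 0.19, Piezo1 from 40.1 to 53.6 CPM, log2 fold change 0.41 ± 0.13, Tmem63a had 0.29 ± 0.16 and Trpv2 0.19 ± 0.12. The median was 0.36 without Mattress 2 (adjusted p = 0.00658) and 0.18 without Mattress 3 (adjusted p = 0.0782). TGF-beta response genes had 16 of 19 members higher, with a median of 0.27 and within-batch medians of 0.29, 0.02 and 0.26. Camera's adjusted p was 0.00943, or 0.53 with an estimated correlation, and 0 passed adjusted over the list alone. Id3, Klf10 and Tgif1 had 0.58 ± 0.16, 0.45 ± 0.13 and 0.52 ± 0.17. The list's median was 0.14 without Mattress 1 (adjusted p = 0.0111), 0.11 without Running 1 (adjusted p = 0.0134) and 0.14 without Running 4 (adjusted p = 0.0504). Matrix remodelling enzymes had 21 of 27 members higher, with a median log2 fold change of 0.40 and within-batch medians of 0.64, 0.32 and 0.27. The list had a camera adjusted p of 0.00886 (adjusted p = 0.53 with an estimated correlation), and 0 passed adjusted over the list alone. The crosslinker Tgm2 went from 73.0 to 129 CPM, log2 fold change 0.85 ± 0.22, Timp1 had 0.76 ± 0.22, Mmp9 2.11 ± 0.73 and Mmp19 0.85 ± 0.32. Its median was 0.24 without Mattress 1 (adjusted p = 0.01), 0.25 without Running 1 (adjusted p = 0.0107) and 0.26 without Running 2 (adjusted p = 0.00223). Mitotic genes of the G2/M list had 34 of 34 members lower, with a median of -0.32 and within-batch medians of -0.77, -0.01 and -0.45. Camera's adjusted p was 6.58e-10, or 0.631 with an estimated correlation, and 0 passed adjusted over the list alone. Tpx2, Birc5, Hmmr and Plk1 had -0.43 ± 0.15, -0.55 ± 0.20, -0.53 ± 0.21 and -0.42 ± 0.16. The list's median was -0.21 without Mattress 1 (adjusted p = 7.58e-06) and -0.21 without Running 1 (adjusted p = 6.91e-06). All 34 were at least as high in melanoma cells as in these cells. Efferocytosis and lysosome genes had 25 of 28 members higher, with a median of 0.16 and within-batch medians of 0.14, 0.43 and 0.15. Camera's adjusted p was 0.00856, or 0.631 with an estimated correlation, and 0 passed adjusted over the list alone. The cholesterol carrier Npc1 had 0.41 ± 0.12, the scavenger receptor Cd36 0.48 ± 0.15, Ctsl 0.40 ± 0.15 and Abca1 0.32 ± 0.15. Its median was 0.09 without Mattress 2 (adjusted p = 0.166) and 0.09 without Running 4 (adjusted p = 0.0488). A further 5 lists that passed, of collagens, neutrophil state, dedifferentiated melanoma, type I interferon response and G1/S genes, are not described.

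T cells address whether running altered antitumour immunity. Of killer cell genes, none of which passed, granzyme B, Gzmb, went from 247 to 134 CPM, log2 fold change -0.79 ± 0.28, Nkg7 from 671 to 402 CPM, log2 fold change -0.71 ± 0.32. Klrd1 had -0.98 ± 0.35 and Gzma -1.22 ± 0.73. In batch B only, a fit with 1 mattress library, the value for Gzma was the other way, at 3.24. Cytotoxicity and activation genes had 12 of 14 members lower, with a median of -0.46 and within-batch medians of -0.50, -1.22 and -0.03. Camera's adjusted p was 0.0232, or 0.784 with an estimated correlation, and 0 passed adjusted over the list alone. Their median was -0.50 without Mattress 1 (adjusted p = 0.135), -0.35 without Mattress 2 (adjusted p = 0.0629), -0.23 without Mattress 3 (adjusted p = 0.114), -0.45 without Running 1 (adjusted p = 0.167) and -0.36 without Running 2 (adjusted p = 0.145). Immediate early genes had 20 of 21 members higher, with a median log2 fold change of 0.45 and within-batch medians of 0.39, 0.75 and 0.42. Camera's adjusted p was 8.99e-05, or 0.784 with an estimated correlation, and 1 passed adjusted over the list alone. Klf4, a transcription factor of quiescence, went from 46.8 to 112 CPM, log2 fold change 1.22 ± 0.31, Fosb had 1.14 ± 0.36, Maff 0.97 ± 0.40 and Zfp36 0.77 ± 0.32. Its median was 0.26 without Mattress 2 (adjusted p = 0.027). TGF-beta response genes had 7 of 8 members higher, with a median log2 fold change of 0.59 and within-batch medians of 0.45, 0.35 and 0.64. Camera's adjusted p was 0.00165, or adjusted p = 0.784 with an estimated correlation, and 1 passed adjusted over the list alone. Pmepa1 went from 83.8 to 153 CPM, log2 fold change 0.93 ± 0.25, Tgfb1 had 0.60 ± 0.25, Tgif1 0.61 ± 0.26 and Smad7 0.58 ± 0.28. The list's median was 0.40 without Mattress 4 (adjusted p = 0.0931). A further list that passed, of G2/M genes, lost the call without 5 single libraries, as the cytotoxicity list did, and is not described. For T cells edgeR called 0 of 4306 genes, while 184 higher and 154 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.628. DESeq2 and limma-voom called 0. The genes Klf9, Btbd9 and Xpr1 had 1.503 ± 0.38, 1.24 ± 0.34 and 1.19 ± 0.34, and Trappc2l, Gulp1, Malsu1, Ube2a and Mrpl14 -0.92 ± 0.27, -1.67 ± 0.52, -0.86 ± 0.27, -0.73 ± 0.23 and -0.81 ± 0.26. Lmna had 0.22 ± 0.33. T cells of Mattress 1 and Running 1 lay mostly in separate clusters, of which they made up 96.9% and 88.2%. A cluster with Gzmc and Klrd1 held 10.7% ± 12.4 of mattress T cells (28.4% in Mattress 2) and 5.05% ± 5.89 with running (SD). T cell values thus mix clusters.

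Neutrophils, dendritic cells and NK cells were compared for the same question with fewer cells. A cluster with Camp and Ngp among its top genes held 8.48% ± 9.25 of mattress neutrophils (SD, n = 4) and 32.1% ± 30.3 with running (SD, n = 5), so values for neutrophils mix clusters in unequal parts. Among neutrophils, Bcl3, an NF-kB cofactor, was 21.2 ± 5.08 CPM on the mattress (SD, n = 4) and 59.2 ± 15.5 CPM with running (SD, n = 5), a log2 fold change of 1.46 ± 0.33, Stfa1 had 3.04 ± 0.77, Chil3 3.12 ± 0.88, Agap1 2.29 ± 0.52, Adpgk 1.84 ± 0.52 and Ccl5 -2.08 ± 0.61. Hspb1, Eci1, Pdcd5 and Nupr1 had -1.81 ± 0.59, -1.12 ± 0.40, -0.77 ± 0.28 and -1.35 ± 0.49. In neutrophils edgeR called 0 of 6057 genes, while 134 higher and 48 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.9996. DESeq2 and limma-voom called 0. In dendritic cells Tnfrsf4, the costimulatory receptor OX40, was 42.9 ± 8.76 CPM on the mattress (SD, n = 4) and 18.4 ± 3.95 CPM with running (SD, n = 5), a log2 fold change of -1.20 ± 0.25, AW112010 had -1.37 ± 0.28, Hspb1 -1.89 ± 0.43, Vegfb -1.21 ± 0.29 and Polr2j -0.73 ± 0.18. Amz1, Tmem222, Slc35f6, Ap2a2 and Clasp2 had 1.46 ± 0.37, 0.88 ± 0.26, 1.37 ± 0.40, 0.71 ± 0.21 and 1.02 ± 0.30. For dendritic cells edgeR called 0 of 6054 genes, while 122 higher and 177 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.784. DESeq2 and limma-voom called 0. NK and innate lymphoid cells were numerous enough in 3 mattress and 4 running libraries, all of batches B and C. A cluster of theirs, with 9 melanoma markers raised, held 95.8% to 100% of them in batch B and 3.03% to 28.9% in batch C. Their values thus mix clusters and batches. The transcription factor gene Runx1 was 35.4 ± 18.2 CPM on the mattress (SD, n = 3) and 159 ± 46.1 CPM with running (SD, n = 4), a log2 fold change of 2.06 ± 0.45, and Hes1 had 1.65 ± 0.42, Cltc 1.08 ± 0.29, Esyt1 1.57 ± 0.43 and Wnk1 1.08 ± 0.30. Trmt112, Atp5o, Cfap20, Tiprl and Pam16 had -0.92 ± 0.29, -0.74 ± 0.27, -1.20 ± 0.47, -0.93 ± 0.38 and -1.06 ± 0.44. For NK and innate lymphoid cells edgeR called 0 of 2033 genes, while 53 higher and 12 lower had an unadjusted p below 0.05. The smallest adjusted p was 0.997. DESeq2 and limma-voom called 0.

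Whole libraries were compared as a view that does not depend on cell classes. Nfkbia, the inhibitor that NF-kB induces, was 86.5 ± 29.4 CPM on the mattress (SD, n = 4) and 152 ± 34.3 CPM with running (SD, n = 5), a log2 fold change of 0.81 ± 0.14, the kinase gene Pim1 had 1.03 ± 0.19, Sdc3 1.02 ± 0.19, Kdm6b 0.52 ± 0.11 and Slc20a1 0.61 ± 0.12, each with edgeR's adjusted p = 0.259. Zfp560, Zswim7, Snhg12, Xpa and Hddc2 had -0.59 ± 0.09, -0.61 ± 0.10, -0.70 ± 0.12, -0.52 ± 0.09 and -0.62 ± 0.11. Here edgeR called 0 of 16737 genes at an adjusted p below 0.05, while 1260 higher and 1399 lower genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.259. DESeq2 called 216 higher and 202 lower genes, and limma-voom called 0. Fibrillar collagen and matrix genes had 23 of 23 members higher and a median of 1.20, within batches 3.49, 2.25 and -0.11 (camera's adjusted p = 1.5e-10, and adjusted p = 0.412 with an estimated correlation, and 0 passed adjusted over the list alone). Thbs1, Tnc, Col1a1 and Col6a1 had 1.41 ± 0.38, 1.81 ± 0.56, 1.55 ± 0.52 and 1.33 ± 0.46. That median was 0.71 without Mattress 1 (adjusted p = 4.37e-07) and 0.71 without Running 1 (adjusted p = 1.41e-07). Of the 35 lists 18 passed, 16 of them higher with running, and each lost the call with an estimated correlation. Values of a whole library also carry its cell shares, and melanoma cells were 42.9% of cells with running and 59.2% on the mattress.

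Whether a list changed differently in tumour and stromal cells was tested directly for melanoma cells against macrophages and monocytes, and against fibroblasts. No list passed, and the smallest adjusted p was 0.270, for matrix remodelling enzymes against macrophages and monocytes, at a difference of -0.18 on the log2 scale (exact permutation p = 0.00794, the smallest the design can give). After adjustment over the lists tested a single list at that p cannot pass, so the lack of calls says little.

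The mCherry transcript was used to look at melanoma RNA counted in other cells. The feature was counted in the 7 libraries labelled B16F10-mCherry and is missing from the features of the other 2, so it cannot test the cell line labels. Melanoma cells held 93.1 ± 16.3 CPM of mCherry (SD, n = 7), with 104 ± 17.6 on the mattress (SD, n = 3) and 84.6 ± 9.86 with running (SD, n = 4). Macrophages and monocytes held 13.2 CPM, fibroblasts 12.2, endothelial cells 12.9, dendritic cells 16.5, T cells 30.1 and neutrophils 34.98, and unnamed cells held 83.6. After thinning cells to 1000 UMIs, 8.38% of melanoma cells had an mCherry UMI, against 1.24% of fibroblasts, 3.29% of neutrophils and 6.72% of unnamed cells. Thinned to 2000 UMIs, these shares were 16.7%, 2.32%, 5.78% and 16.55%, with 72.6% of neutrophils and 60.8% of unnamed cells left out as too shallow. The median depth per library before thinning, averaged over the 7 libraries, was 23793 UMIs in melanoma cells, 9616 in fibroblasts and 1642 in neutrophils. The melanosome gene Pmel was likewise 2055 CPM in melanoma cells and between 303 and 1120 CPM in host classes. Melanoma transcripts were thus counted in host classes as well. Whether they came from free RNA, from doublets or from an exchange between tumour and stroma was not tested.

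**Figure D4:**
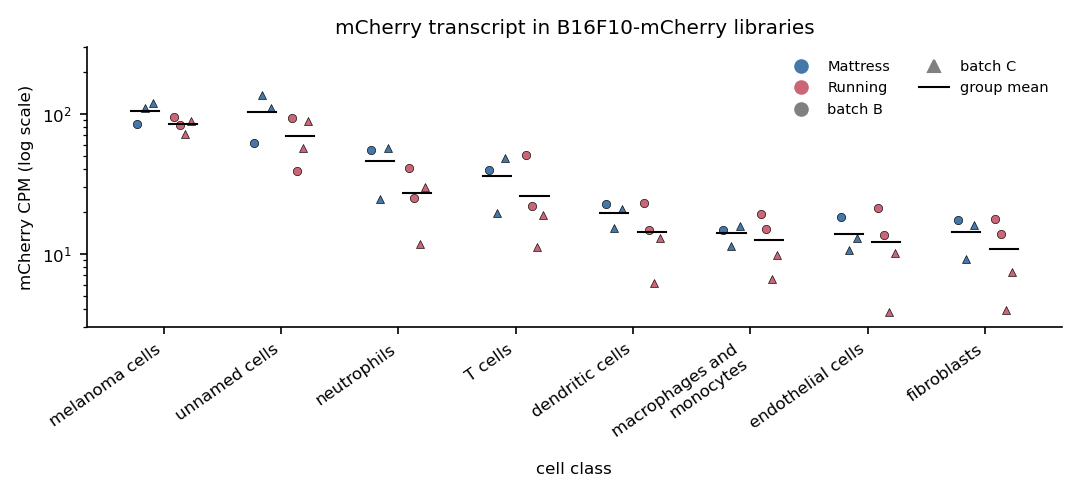
mCherry CPM (log axis) per class in the 7 B16F10-mCherry libraries, coloured by treatment. Melanoma cells averaged 93.1 CPM and macrophages and monocytes 13.2 CPM.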

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

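The tests for a factor of the whole library behind respiratory chain genes, for a batch behind interferon genes, for unnamed cells and for a batch behind the melanoma share, and all counts of other splits were chosen after the results were seen. A library is given here when its gap to the nearest library of its group took an unusually large part of the group's range by Dixon's test. This held in 62 of 855 groups tested, 61 of which are given here, and chance alone gives about 1 in 20. Mattress 1 accounted for 17 and Running 1 for 15, the pair of batch A. For single genes the values below are log2 of CPM plus 2. A value of 1 therefore stands for no counts, and gaps near it are compressed.

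Mattress 1 stood apart in macrophages and monocytes among named non-melanoma cells at 60.3% (others 35.9 to 40.1). List means of Mattress 1, in log2 CPM, stood apart for mechanosensitive channels and receptors at 2.26 (others 2.65 to 2.71) in melanoma cells, and mechanosensitive channels and receptors at 2.58 (others 3.001 to 3.02) in whole libraries, and matrix remodelling enzymes at 2.996 (others 4.19 to 4.37) and TGF-beta response at 4.74 (others 5.17 to 5.24) in macrophages and monocytes. In melanoma cells of Mattress 1, gene values in log2 CPM stood apart for Gpc1 at 6.67 (others 6.25 to 6.29), Adgre5 at 4.64 (others 5.30 to 5.42) and Thbs1 at 1.32 (others 2.69 to 2.80). Genes apart in whole libraries of Mattress 1 were Nos2 at 1.14 (others 1.44 to 1.47). For macrophages and monocytes, Mattress 1 differed in Zfp560 at 5.04 (others 4.67 to 4.71). In fibroblasts of Mattress 1, gene values in log2 CPM stood apart for Smim41 at 5.56 (others 4.77 to 4.87), Col1a1 at 12.13 (others 12.79 to 12.83), Mcm5 at 2.39 (others 4.17 to 4.42) and Itgam at 1 (others 1.83 to 1.91). Genes apart in endothelial cells of Mattress 1 were Dll1 at 4.80 (others 5.55 to 5.69) and Pgk1 at 8.94 (others 9.50 to 9.56). For T cells, Mattress 1 differed in Maff at 1 (others 5.02 to 5.27). Mattress 2 stood apart in 28029 barcodes (others 10419 to 12111) and 337 M UMIs (others 139.5 to 154, M for mega). List means of Mattress 2, in log2 CPM, stood apart for type I interferon response at 5.25 (others 4.39 to 4.53) in fibroblasts. In melanoma cells of Mattress 2, gene values in log2 CPM stood apart for Ifi44 at 2.82 (others 1.17 to 1.38) and Camp at 1.10 (others 1). Genes apart in whole libraries of Mattress 2 were Cks2 at 8.82 (others 8.02 to 8.11). For macrophages and monocytes, Mattress 2 differed in Tgif1 at 7.55 (others 6.75 to 6.87). In fibroblasts of Mattress 3, gene values in log2 CPM stood apart for Ccl8 at 7.43 (others 6.82 to 6.86) and Lmnb1 at 4.68 (others 5.21 to 5.29).

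In melanoma cells of Running 1, gene values in log2 CPM stood apart for Trim30a at 3.25 (others 1.78 to 2.14), Adgre5 at 4.63 (others 5.61 to 5.84), Atp5o at 9.16 (others 9.76 to 9.96), Klf2 at 3.90 (others 4.89 to 5.28), Jund at 6.86 (others 7.95 to 8.14) and Ccl4 at 1.38 (others 2.43 to 2.80). Genes apart in whole libraries of Running 1 were Adgre5 at 4.88 (others 5.76 to 5.93) and Cenpf at 7.39 (others 6.73 to 6.90). For macrophages and monocytes, Running 1 differed in Tmem63a at 4.55 (others 4.18 to 4.26), Timp1 at 4.89 (others 5.84 to 6.17) and Tgif1 at 7.02 (others 7.59 to 7.79). In fibroblasts of Running 1, gene values in log2 CPM stood apart for Rpa1 at 3.75 (others 4.62 to 4.97) and Atp5j at 7.92 (others 8.42 to 8.61). Genes apart in endothelial cells of Running 1 were H2-Q7 at 5.84 (others 2.75 to 3.31). List means of Running 2, in log2 CPM, stood apart for senescence-associated secretory genes at 6.27 (others 6.75 to 6.89) in fibroblasts, and glycolysis at 7.96 (others 7.43 to 7.51) in endothelial cells. In macrophages and monocytes of Running 2, gene values in log2 CPM stood apart for Cd44 at 8.82 (others 9.003 to 9.08). In macrophages and monocytes of Running 3, gene values in log2 CPM stood apart for Ctsl at 10.80 (others 11.21 to 11.32). Running 4 stood apart in dendritic cells among all cells at 2.29% (others 1.05 to 1.32), erythroid cells among all cells at 4.55% (others 0.218 to 0.7), NK and innate lymphoid cells among all cells at 1.16% (others 0.182 to 0.431) and erythroid cells among named non-melanoma cells at 8.58% (others 0.627 to 2.36). In melanoma cells of Running 4, gene values in log2 CPM stood apart for Fads6 at 4.88 (others 4.51 to 4.60) and Cxcr2 at 1.20 (others 1.16 to 1.17). Genes apart in whole libraries of Running 4 were H2-Eb1 at 6.85 (others 5.92 to 6.07). For T cells, Running 4 differed in Klf9 at 5.98 (others 5.34 to 5.47). List means of Running 5, in log2 CPM, stood apart for fibrillar collagens and matrix at 5.65 (others 6.45 to 6.78) and growth factors and stromal ligands at 2.96 (others 3.39 to 3.54) in whole libraries. In melanoma cells of Running 5, gene values in log2 CPM stood apart for Ifi44 at 1.26 (others 1.14 to 1.18), S100a8 at 4.61 (others 1.91 to 2.62) and Camp at 3.45 (others 1.004 to 1.13). Genes apart in whole libraries of Running 5 were Id3 at 4.57 (others 5.05 to 5.19). For macrophages and monocytes, Running 5 differed in Ccl4 at 9.96 (others 8.74 to 9.09). In endothelial cells of Running 5, gene values in log2 CPM stood apart for Mall at 6.50 (others 6.23 to 6.29) and Ptn at 3.99 (others 4.95 to 5.17).

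Lower respiratory chain transcripts with running, seen in each of 5 classes, were weighed against technical explanations. Running 1 alone is argued against, since without that library the list was still called lower in 5 of 5 classes with camera's preset correlation. The medians were then -0.18, -0.25, -0.24, -0.22 and -0.23 in place of -0.31, -0.47, -0.43, -0.33 and -0.43. With an estimated correlation over all libraries, however, the list was called in 0 classes. With cell line as a term, leaving out Running 1 also takes Mattress 1 out of the comparison. This check therefore cannot tell the pair of batch A apart. A factor of the whole library shared by its cell classes stays open: in 6 of the 9 libraries the list's deviation from its group mean had the same sign in all 5 classes. Loss of short transcripts in general cannot be told apart from a change of the respiratory chain, since genes chosen to be near in length and expression, yet longer (711 to 744 bases against 576.5) and less expressed by median in every class, had median changes of -0.15, -0.08, -0.08, -0.10 and -0.17 and lay above the bound in 2 of 5 classes. Ribosomal protein genes, with medians of -0.38, -0.47, -0.44, -0.39 and -0.35, may share such a library factor, and an effect of running stays open and untested beyond the comparison itself.

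Interferon-stimulated genes were highest in melanoma cells of Mattress 2, at 4.24 log2 CPM against 2.20 to 3.20 in the other libraries. RNA from host cells stays open: macrophage markers there averaged 1.59 log2 CPM (highest elsewhere 2.57), but these gauge its amount, not its interferon content. A batch is argued against, since the 2 running libraries of the batch lay below the 6 libraries of other batches by the signed difference -0.60. The mattress group as a whole cannot be told apart from that library alone, since without it the median was -0.14 with an adjusted p of 0.0823, lower but no longer called. Mattress 2 also stood apart for the same genes in fibroblasts, and what sets that library apart stays open, with no label to test it by.

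The lower share of melanoma cells with running was weighed against the way cells were named and against batch. Melanoma cells left in unnamed clusters are argued against as the whole cause: with unnamed cells counted as melanoma cells, the difference was -13.1 percentage points (74.8% ± 10.5, n = 4, and 61.7% ± 10.4, n = 5, exact p = 0.143). A batch is argued against, since the difference was negative in 3 of 3 batches. The share did not pass its exact test (p = 0.135, n = 4 and 5). Nor did it pass when libraries were relabelled within batches (exact p = 0.0556, where the smallest possible is 0.0278). Chance is therefore not excluded, and a lower yield of melanoma cells from dissociation stays open and was not tested.

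Other splits of the 9 libraries were compared with the real one. For genes called by edgeR the real split gave 0 in each class. Any split reaches a count of 0, so the test says nothing about chance there: 100 of 100 splits gave as many in melanoma cells, whole libraries, macrophages and monocytes, fibroblasts, endothelial cells, T cells, neutrophils and dendritic cells, as did 35 of 35 for NK and innate lymphoid cells. The highest other counts were 2154, 1362, 1737, 1138, 646, 499, 1572, 899 and 351 in that order, which points to a structure of the samples. In melanoma cells and whole libraries the highest came from the split that sets batch C apart. The same split gave 1053 genes in macrophages and monocytes, 1109 in fibroblasts and 567 in endothelial cells. In NK and innate lymphoid cells the highest came from setting batch B apart. For lists, the real split gave 7 in melanoma cells, and 75 of 100 splits gave as many (highest other 22). The counts were 11 and 59 (23) in macrophages and monocytes, 12 and 41 (22) in fibroblasts, 7 and 68 (16) in endothelial cells, 5 and 61 (13) in T cells and 18 and 45 (30) in whole libraries. Chance is not excluded for any of these counts of lists.

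Relabelling within batches, with batch as a covariate, removes that structure. Genes at an unadjusted p below 0.05 then numbered 3255 in melanoma cells (highest other split 2215), 4217 in whole libraries (3593), 2291 in macrophages and monocytes (1855), 1405 in fibroblasts (1154) and 938 in endothelial cells (833), and in each only 1 of 36 splits, the real one, reached the count. This argues against chance for these counts only at 1 of 36, the smallest share the test can give. That share was not adjusted over the classes, and classes of the same libraries are not independent of each other. In T cells 3 of 36 splits reached the 582 of the real one (highest other 647). In neutrophils 2 of 36 reached 495 (554) and in dendritic cells 2 of 36 reached 649 (722). In these classes chance is not argued against. NK and innate lymphoid cells had 213 (197) and too few splits, 18, for a share under 0.05. This is consistent with an effect of running that is small beside the spread between batches, as a hypothesis, since the batches were read from the same data and single genes still did not pass, except 2 in endothelial cells.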

How the results depend on the processing

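The alternatives that use batches, that leave out genes at least as high in melanoma cells, that relabel within batches and that count unnamed cells in the denominator were chosen after the data were examined. Among alternative counts of genes, 181 stayed within 1.5 times the reported count (or at 0) and 25 did not, and among counts of lists 90 stayed and 37 did not. For named genes, 7483 alternative values kept their direction and side of the threshold, 218 passed where the reported value did not, 105 changed sign without passing and 1 reversed. For lists that passed, 935 values kept their call, 166 lost it with camera's direction kept and 19 reversed in that direction. The median turned sign in some of those that lost the call, as for type I interferon response in macrophages and monocytes (0.0523 without Mattress 2) and melanocyte differentiation in fibroblasts (0.122 without Mattress 2) and endothelial cells (0.222 without Mattress 2). Differences of shares kept their sign in 391 cases and changed it in 26, and none passed its test. Where values below moved, the cause was not tested unless stated.

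By DESeq2, genes numbered 158 in melanoma cells, 418 in whole libraries, 89 in macrophages and monocytes, 59 in fibroblasts and 4 in endothelial cells (Cavin1, Grcc10, Kcne3 and Rgcc, with Kcne3 named after its value was seen). With no filter beyond 1 count, endothelial cells had 26, T cells 13, neutrophils 42 and dendritic cells 14. With batch as a covariate, endothelial cells had 2. In batch B only, melanoma cells had 682, whole libraries 1645, macrophages and monocytes 477, fibroblasts 466, endothelial cells 144, T cells 75, neutrophils 94, dendritic cells 63 and NK and innate lymphoid cells 8, with a lone mattress library assumed to vary like the running ones. In batch C only, melanoma cells had 9, macrophages and monocytes 160, neutrophils 20 and endothelial cells 1, Ccl21a, which has near-identical copies and was named after its value was seen. Leaving out single libraries gave 0 to 1 gene in endothelial cells (Ptn, without Mattress 4).

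Replicate numbers did not pair the libraries: in melanoma cells the correlation of deviations was 0.52, 0.59 and 0.50 for numbers 1, 2 and 4 but -0.33 for number 3, and not every library correlated best with its own number. With the replicate block, 13 lists were called in melanoma cells and 1 gene in neutrophils, Elane at a log2 fold change of 8.60, named after its value was seen; other counts stayed within 1.5 times.

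With an estimated correlation in camera, 0 lists were called in melanoma cells, whole libraries, macrophages and monocytes, fibroblasts, endothelial cells and T cells, and fry called 2 in melanoma cells and 0 in the other 5, the preset correlation being the choice that carries these calls. The stricter cell filter gave 12 in melanoma cells, at most 300 cells per library 5 in macrophages and monocytes, B16F10-mCherry libraries only 11 and batch as a covariate 4 in endothelial cells, and doublets kept 3 in T cells. In batch B only the counts were 21 in melanoma cells, 17 in macrophages and monocytes, 16 in endothelial cells and 10 in T cells. In batch C only they were 23 in macrophages and monocytes, 20 in fibroblasts and 13 in endothelial cells. Without genes at least as high in melanoma cells they were 6 in macrophages and monocytes, 7 in fibroblasts and 4 in endothelial cells, with fewer genes tested. Leaving out single libraries gave 5 (without Mattress 2) to 13 (without Running 5) in melanoma cells, 7 (without Mattress 3) to 15 (without Mattress 1) in fibroblasts, 2 (without Mattress 2) to 12 (without Mattress 4) in endothelial cells and 3 (without Mattress 2) to 6 in T cells.

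Medians of lists reversed in batch C only as follows. Collagens went to -0.77 in melanoma cells, -0.0489 in whole libraries, -0.59 in macrophages and monocytes and -0.0206 in fibroblasts. Type I interferon response went to 0.40 in macrophages and monocytes, 0.42 in fibroblasts and 0.28 in endothelial cells. MHC class I presentation went to 0.0457 in endothelial cells, senescence-associated secretory genes to 0.0013 in fibroblasts and angiogenic endothelium to -0.0497 in whole libraries. Angiogenic endothelium at -0.00072 in fibroblasts and cytotoxicity at -0.0535 in T cells turned by camera's direction, not by the median. In batch B only, G2/M genes went to 0.13 in whole libraries, G1/S to 0.20 and neutrophil state to -0.30 in macrophages and monocytes, and Gzma in T cells to 3.24, while neutrophil state in melanoma cells, at 0.14, turned by camera's direction alone. G1/S in macrophages and monocytes went to 0.0712 in B16F10-mCherry libraries only, and without single libraries lay between -0.15 and 0.0785.

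Differences of shares are in percentage points unless on the logit scale. B16F10-mCherry libraries only gave -0.135 for endothelial cells, -0.197 for T cells and 5.40 for macrophages and monocytes among named cells other than melanoma cells. The logit gave -0.0793 for mural cells, -0.111 for NK and innate lymphoid cells and -0.256 for T cells. For NK and innate lymphoid cells, doublets kept gave -0.00571, the stricter filter -0.0447 and relabelling within batches -0.0188. For macrophages and monocytes among named cells, doublets kept gave 0.348 and unnamed cells in the denominator 2.97. Leaving out single libraries gave -0.0517 to 0.395 for dendritic cells, -0.0994 to 0.791 for endothelial cells, -1.18 to 0.0516 for erythroid cells, -0.0989 to 0.174 for mural cells, -0.160 to 0.0861 for NK and innate lymphoid cells, -0.283 to 0.356 for T cells, -2.10 to 7.11 for unnamed cells and -4.57 to 3.58 for macrophages and monocytes among named cells. mCherry with doublets kept was 34.9 CPM in endothelial cells and 72.4 CPM in neutrophils. With thinning to 2000 UMIs, the share of cells with an mCherry UMI rose beyond the spread between libraries in all 8 classes, unnamed cells among them, as more UMIs per cell were kept.

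Some alternatives gave no value: resolution 0.5 changes nothing in whole libraries and left no mural class, and drawing at most 300 cells changes nothing in T, NK and dendritic cells, where no library holds more. Libraries of batch A held too few NK cells to be fitted, so leaving them out changed no gene count there.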

Other observations

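No test of this part was planned before the data were examined. Macrophages and monocytes held several states. A cluster led by Pf4, Arg1 and Cxcl3 was 13.9% ± 5.21 of the class on the mattress and 22.4% ± 7.84 with running (SD, exact p = 0.143, n = 4 and 5). A cluster with Rsad2, Ifit1 and Cxcl10 was lower with running (exact p = 0.0556) and drew 48.4% of its cells from Mattress 2. A fibroblast cluster led by Prg4, the lubricin gene, was 9.61% ± 7.56 and 20.05% ± 8.01 (exact p = 0.0952), and a neutrophil cluster with the granule genes Camp and Ngp was 8.48% ± 9.25 and 32.1% ± 30.3 (exact p = 0.183). None of 36 clusters passed after adjustment, with the smallest adjusted p at 0.619. A single cluster at the smallest p the exact test can give could not pass.

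Xist, transcribed from the inactive X chromosome, was 3.80 CPM in melanoma cells and between 559 and 873 CPM in T cells, dendritic cells, endothelial cells, fibroblasts, and macrophages and monocytes. Neutrophils had 275 CPM and unnamed cells 84.5 CPM. Among unnamed clusters, one carried the skeletal muscle genes Acta1 and Tnnt3 at a median of 1300 UMIs, and one the keratinocyte genes Krt14 and Krt10, with 89.0% of its cells from Running 3. Another drew 89.4% of its cells from Mattress 1.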
